A study of Mus musculus with 4 samples.

How the data were processed

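The series describes bulk RNA-seq of mammary tumours grown in Balb/c mice from 4T1 cells, a mouse mammary carcinoma line. Per the labels' protocols, 500000 cells were placed in the mammary fat pad, and established tumours were treated with the solvent DMSO or with vismodegib, an inhibitor of the Hedgehog receptor component Smoothened, at 2 mg per mouse, 3 times a week for 3 weeks. The labels give 4 tumour samples, 2 per group. Tumours were frozen, RNA was extracted with Trizol, and libraries were read as paired ends on an Illumina HiSeq.

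The authors deposited 2 tables over the same 3800 gene names. The first holds estimated counts per gene as deposited, not normalized; 136 values of DMSO replicate 1 and 156 of DMSO replicate 2 are not whole (further than 1e-9 from a whole number). The second holds RPKM values (read counts scaled for gene length and library size) that the authors computed before deposit. Per the submitters' processing notes, bcl2fastq 2.17, cutadapt, STAR, HISAT2, SAMtools and Partek were used and the build was mm10. Which of the aligners made these tables, the annotation behind them, the filters and the strand setting are not given in the sources used here. The gene names follow human nomenclature, so no mm10 coordinates are given for the genes of the tables.

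Columns were assigned to samples by name. Each table has 2 value columns named for DMSO replicates 1 and 2, which match the DMSO samples' titles. The other 2 value columns of each table are named for GANT61, an inhibitor of GLI transcription factors. No sample's labels name that compound. Because the other columns name a treatment that the series does not describe, the tables may belong to another experiment, and then the DMSO columns would be its controls. The values are given as those of the columns named DMSO, under that limit. The GANT61 columns were assigned to no sample and were not used in any step. No column could be assigned to the 2 vismodegib samples, so the comparison of vismodegib with DMSO is not analysed here. The edgeR test, the gene list tests and the rule for named genes that were fixed before the data were examined for that comparison were therefore not run. Gene lists fixed before the data were examined are described by the levels of their members. The genes with the highest values are named as well, a choice made after their values were seen. Some genes are not reported here.

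Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The DMSO libraries were compared over genes with a summed count of at least 10, after rounding to whole counts, by a chi-square test against the common ratio of the column totals. Each gene was also tested with a two-sided exact binomial test against that ratio, with Benjamini-Hochberg adjustment. The exact test was tried on counts simulated for this comparison, with as many changed genes raised as lowered. It recovered 34% of 100 genes changed 2-fold and 71% of 100 genes changed 4-fold. Of the 1061 genes tested, which include changed ones, 8 unchanged genes were called falsely. Intervals on summed counts are exact Poisson intervals and those on shares are Wilson intervals, both at 95%. They cover counting error only, since reads without molecular identifiers are not independent molecules.

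The read total used for the RPKM values was recovered from the tables. Count divided by RPKM is proportional to gene length times read total, so the largest read total was sought that turned the 400 shortest genes into whole numbers of bases (within 0.05). The search ran from 2000000 to 60000000 reads. Gene names were compared with mouse symbols and synonyms of GENCODE M21 and RefSeq without regard to case. Alternatives to the count minimum, the rounding, the common ratio and the denominators were chosen after seeing the data.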

Results

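The series was designed to compare the transcriptomes of 4T1 mammary tumours from mice given the solvent DMSO with those of mice given vismodegib, 2 samples per group. Values could be assigned to the DMSO samples only, by column name, in tables whose other columns name a treatment outside the series. Whether these DMSO columns hold this series' tumours could not be checked beyond their names. No expression value is reported for vismodegib tumours, and no treated tumour was compared with a control. The results below describe the 2 DMSO libraries.

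The column totals were 201244 estimated counts for DMSO replicate 1 and 223268 for DMSO replicate 2. Of the 3800 gene names, 2340 had at least 1 count in replicate 1 and 2394 in replicate 2. At least 10 counts in both libraries were reached by 727 genes, and at least 100 in both by 196. In both libraries 842 genes were listed at 0. With an upper limit of 3 counts for a count of 0, which is lower than that of the two-sided exact Poisson interval used for summed counts, a gene listed at 0 allows a share of up to 0.00149% of the column total in replicate 1 and 0.00134% in replicate 2.

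The column totals were a small part of the reads behind the RPKM values. The RPKM values implied read totals of 10996915 reads for replicate 1 and 12302840 for replicate 2. The totals were searched for on the 400 shortest genes of each library. Of the next 400 genes, which were not used in the search, 100% came out at a whole number of bases in each library, where chance would give 10%. The rows of the table held 1.83% of the implied total in replicate 1 and 1.81% in replicate 2. The rows may be a part of a larger table, and the remaining reads are not analysed here. Every share of counts given for genes or lists is therefore a share of these rows unless the implied total is named, and a gene without a row is not thereby shown to lack reads.

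One gene held the largest share of the counts in the rows analysed here. EIF1, a translation initiation factor, had 92483 counts in replicate 1 and 103075 in replicate 2. This was 46.0% of the column total in replicate 1 (95% Wilson interval 45.7 to 46.2) and 46.2% in replicate 2 (46.0 to 46.4). Of the read totals implied by RPKM it was 0.841% and 0.838%. RNR2, the large mitochondrial ribosomal RNA, followed with 10684 and 11887 counts. Together EIF1 and RNR2 held 51.4% of the column totals, and the 12 genes with the highest counts held 61.0%.

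Other genes with high counts were far below EIF1 and RNR2. YLPM1 had 2553 counts in replicate 1 and 2834 in replicate 2, and APOLD1 had 2419 and 2774. FOXK1, a forkhead transcription factor, had 1582 and 1835 counts. TADA2A, a subunit of histone acetyltransferase complexes, had 1575 and 1646. CRHR2, a receptor for corticotropin-releasing hormone peptides, had 1493 and 1653. TRPC6, a cation channel, had 1406 and 1546. RNR1, the small mitochondrial ribosomal RNA, had 1470 and 1531.

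In the authors' RPKM values, which are scaled for gene length, EIF1 stood at 3597 RPKM in replicate 1 and 3583 in replicate 2, RNR2 at 624 and 620.2, and RNR1 at 140.1 and 130.4. The olfactory receptor gene OR10H5 came next, with 128 and 117 RPKM. INSL3, a peptide hormone of the testis and ovary, had 42.5 and 36.6 RPKM, and CETN3, a centriole protein, had 40.6 and 34.0 RPKM.

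**Figure D1:**
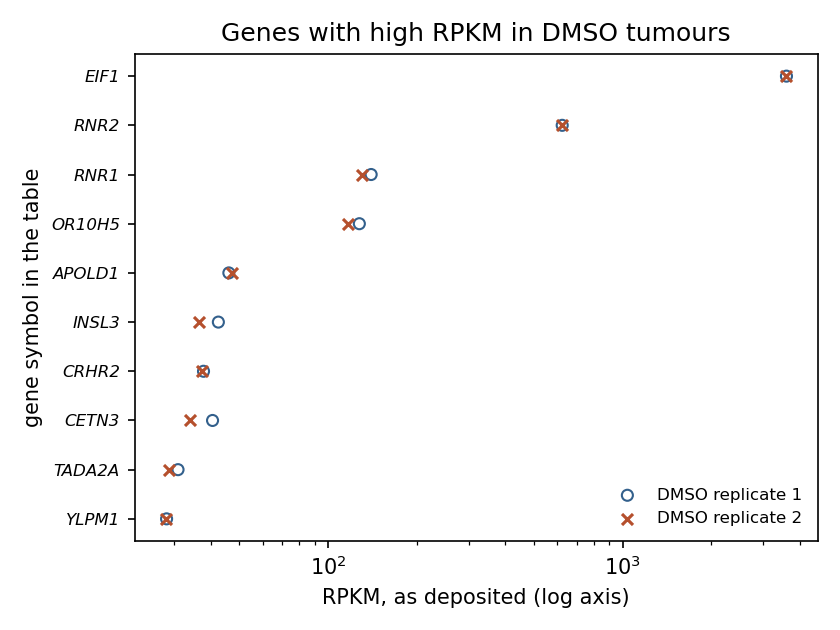
RPKM as deposited (x axis, log scale) of genes with high RPKM in the columns named DMSO (y axis). Circles show DMSO replicate 1 and crosses DMSO replicate 2. EIF1 lies at 3597 and 3583 RPKM, RNR2 at 624 and 620.2, and the others at or below 140.1 RPKM.

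Gene families that occur under these names in human annotation were present. Over all 3800 names, 1063 had a summed count of at least 10, and the median summed count was 2. There were 151 LINC names, of which 37 had a summed count of at least 10, led by LINC00488 with 1107 counts. Of 162 LOC names 38 reached that level, of 113 antisense names 31, and of 67 olfactory receptor genes 19. OR10H5 alone gave 2697 of the 3759 olfactory receptor counts. Among 109 ZNF zinc finger genes 37 reached it, led by ZNF727 with 2223 counts. The 9 ribosomal protein genes in the table held 37 counts together, 0.00872% of all counts in these rows, and 23 of these were in RPL36. Their median summed count was 1. RPL5 and RPS24 were listed at 0 in both libraries. Over the gene names, 2810 matched a mouse symbol or synonym when case was ignored and 990 matched none. The unmatched names held 15.3% of the counts.

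The Hedgehog pathway, the target of vismodegib, was hardly covered. Of the pathway genes chosen beforehand, Gli1, Ptch1, Hhip, Gli2 and Smo had no row, so they are not analysed here. Of 17 pathway components only SPOP, a ubiquitin ligase adaptor, was in the table, with 1 and 2 counts. Of 17 target genes 3 were in the table. BCL2, an inhibitor of apoptosis, had 18 and 22 counts (summed 40, 95% Poisson interval 28.6 to 54.5). CCND2 and BMP4 had 1 summed count each.

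Across all 39 gene lists, 71 of 550 distinct members were in the table, and 16 of these had at least 10 counts in both libraries. Over all 3800 names, 727 reached that level. The 71 members held 1.29% of all counts, and 11 lists had a member at that level. The highest was PGM3, an enzyme of the hexosamine pathway, with 1420 and 1622 counts and 16.7 and 17.0 RPKM. UAP1, the other member of that list in the table, had 1 summed count. Among interferon response genes IFIT1 had 328 and 384 counts, while IFIT2 and IFIT3 had 5 and 4 summed counts and DDX58 was listed at 0. The cholesterol synthesis list had 5 members in the table, all with 10 or more counts in both libraries. Only the interferon response list had as many members in the table, so the remaining lists could not reach that number. In the cholesterol synthesis list FDFT1 had 194 summed counts (95% Poisson interval 168 to 223). HMGCS1 had 49, NSDHL 43, FDPS 26 and SC5D 22.

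Markers of tumour and stromal cells were uneven. Of the 3800 gene names, 842 were listed at 0 in both libraries. A marker at 0 is therefore not set apart from the rest of the table and is not read as absence of its cells. ESRP1, an epithelial splicing regulator, had 94 and 114 counts and was the single member of the epithelial list in the table. Among fibroblast and matrix genes THY1 had 238 and 272 counts and FAP 2 and 2, while DCN and PDGFRA were listed at 0. CSPG4 and TAGLN, markers of pericytes and smooth muscle, had 97 and 132 counts and 52 and 56 counts, while MYH11 of the same list was at 0 and MCAM had 1 summed count. The endothelial list had 1 member in the table, TIE1, with 1 summed count. LOXL2, a collagen cross-linking enzyme of the invasion list, had 23 and 14 counts, and LOX was listed at 0. The skeletal muscle enzyme CKM had 1 and 1 counts, and LEP, the adipose hormone leptin, had 12 and 19.

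Most immune markers in the table were near the counting floor, as were most of its genes. Over all 3800 names the median summed count was 2, and 727 genes had at least 10 counts in both libraries. The low counts of the immune markers therefore do not set them apart from the rest of the table. ADGRE1 and MS4A7, markers of macrophages, had 3 and 2 summed counts. Of the macrophage polarization genes, NOS2 had 3, IRF5 had 2, CCL5 had 8 and TGFB1 had 1 summed counts. The neutrophil marker TREM1 had 2 summed counts, and the T cell markers CD3E and CD5 had 1 and 8. MS4A1, a B cell marker, reached 18 and 17 counts, and EPX, eosinophil peroxidase, 14 and 15. No member of the dendritic cell, regulatory T cell and checkpoint, milk protein, erythroid and lymph node lists was in the table. KIF20A was the only member of the proliferation list in the table, with 7 summed counts.

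No excess over sampling noise was detected between the DMSO libraries as a whole, while 2 single genes were called as differing. Over 1065 genes the chi-square statistic was 1130 on 1064 degrees of freedom (p = 0.0793), or 1.06 per degree of freedom. Across genes, which are not independent replicates, Pearson's r of the log2(count + 1) values was 0.966. Exact binomial tests with Benjamini-Hochberg adjustment called these 2 genes, and 47 genes had an unadjusted p under 0.05. Like the intervals, the chi-square and binomial tests cover counting error only, since reads are not independent molecules. SLAIN2 had 931 counts in replicate 1 and 827 in replicate 2 (adjusted exact p = 0.00375). RFFL had 0.000211 and 15.9 estimated counts (adjusted exact p = 0.0217), fractional values of the kind an estimate gives when it divides reads among genes. The titles of the 2 DMSO samples share a prefix, as do those of the vismodegib samples, and the labels do not say what it stands for. The labels do not say whether the libraries came from separate mice, and the test does not settle it. As a precaution they were counted as 1 sample, and no SD between tumours is given.

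**Figure D2:**
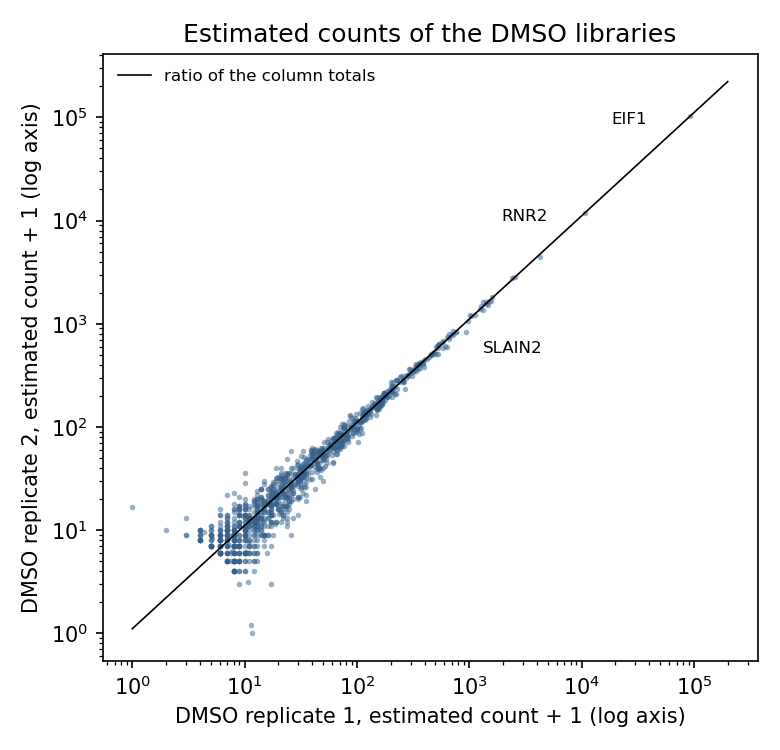
Estimated count plus 1 of DMSO replicate 1 (x axis) and DMSO replicate 2 (y axis), both on log scales. Shown are the 1063 genes with a summed count of at least 10 before rounding. Each point is a gene and the line is the ratio of the column totals, 1.11. The points follow the line up to EIF1 at 92483 and 103075 counts, and SLAIN2 lies below it at 931 and 827.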

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

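All alternatives given here were chosen after seeing the data; those planned for the comparison of vismodegib with DMSO were not run, because no column could be assigned to vismodegib. No paired analysis was possible because columns of only the DMSO group could be assigned to samples. The agreement of the DMSO libraries stayed above p = 0.05 under each alternative tried, with chi-square per degree of freedom from 1.01 (genes with whole counts in both libraries, p = 0.444) to 1.07 (the read totals implied by RPKM as the common ratio, p = 0.0604); the lowest p was 0.0513, at a summed count of at least 5. The share of counts in EIF1 depended on its denominator. It was 46.1% of the column totals, 49.0% with the mitochondrial ribosomal RNAs left out of the total, 54.9% of the summed RPKM and 0.839% of the read totals implied by RPKM, which include reads outside these rows. With 1 library at a time it was 46.0% to 46.2%. The number of genes with enough counts in both libraries was 727 at a minimum of 10, 979 at 5 and 526 at 20. The median gene of the table had 2 summed counts, which limits the precision of its value; why counts were low was not tested.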

Other observations

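All tests in this part were chosen after the result was seen. The tables, deposited as those of mouse tumours, carry human gene names and human gene families. Whether they belong to another experiment, which their other columns leave open, was not tested. Capitalised mouse symbols do not account for this, since 26.1% of the names matched no mouse symbol or synonym. Human RNA as the main source of the counts was examined through the ribosomal protein genes. The ribosomal protein genes, abundant in any human cell, held 0.00872% of the counts in these rows (95% Poisson interval 0.00614 to 0.0120). They make up 0.237% of the gene names. Only 9 of them have a row, and the rows hold 1.83% and 1.81% of the implied read totals of replicates 1 and 2. How the rows were chosen is not known and could set this share, but not the counts inside a row. The 9 rows held 37 counts together, beside implied totals of 10996915 and 12302840 reads. RPL5 and RPS24 were at 0 in both libraries. For these 9 genes, the low counts argue against human RNA as the main source. Whether rows were chosen by their counts was not tested. Counting on a reference other than the mouse one remains a candidate explanation. Counts and RPKM imply a length of 1558 bases for RNR2. The mouse gene mt-Rnr2 (mitochondrial chromosome, 1094 to 2675, GRCm38, GENCODE M21) has 1582. For RNR1 they imply 954 bases, where mt-Rnr1 has 955. This difference of 1 base counts neither for nor against a mouse reference, since no length in another species was compared. If another reference was used, levels such as those of EIF1, OR10H5 or PGM3 may reflect which mouse reads resemble it rather than tumour expression. The same holds for genes listed at 0. No reference of another species was used here, and human RNA as a smaller source of counts stays open.

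The second pattern is the close agreement of the DMSO libraries. One RNA sample sequenced or deposited under both names is consistent with the chi-square of 1.06 per degree of freedom. Libraries simulated with no added variation gave a median of 1.001 in 100 simulations (central 95% 0.925 to 1.063), so the observed value lies near the top of that range. Those with an added coefficient of variation of 5% gave 1.34 (1.18 to 1.80), above the observed value. An added 10% gave 2.27 (1.83 to 5.37) and 20% gave 5.81 (4.49 to 15.5). The observed value thus lay below the range of every setting with added variation. The simulations gave every gene the same added variation, which shows mainly in genes with high counts. Genes with low counts could vary more without moving the ratio as far. Separate tumours with a spread below 5% in the genes of this table cannot be told apart from a single RNA sample under both names. The labels do not name the mice, and no other pair of DMSO libraries gives a scale for the spread between tumours. No biological explanation was tested for either pattern.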
